A study of Mus musculus with 21 samples.

How the data were processed

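Expression was measured in 21 samples of liver or kidney RNA from offspring of control or deficient-diet sires, on NimbleGen arrays of 42575 features with 135054 gene probes and 2550 random probes. RNA had been purified with on-column DNase digestion, per the labels. The probe files hold one-colour Cy3 intensities of single probes as deposited, 2 per sample. On the 5 slides with more than 1 array the sorted intensities of the arrays were nearly identical (largest difference 0.292 log2, on slide 7), so quantile normalization within these slides had preceded deposit. Whether background had been subtracted is not stated. The deposited value table of the authors holds log2 values made with RMA, per the submitters' processing notes, with no version given. In 19 of 21 samples these log2 values equalled, within 0.01, the mean log2 intensity of the 2 deposited arrays, the exceptions being control liver 4 and control kidney 5. The medians of the table's columns were 8.53, 8.61, 8.44, 8.30 and 8.17 for control liver 1 to 5, and 8.50, 8.35, 8.56, 8.50 and 8.69 for deficient-diet liver 1 to 5. They were 9.16, 9.08, 9.13, 9.09, 9.06 and 9.11 for control kidney 1 to 6, and 9.15, 9.13, 9.12, 9.10 and 8.53 for deficient-diet kidney 1 to 5. Scale, centring and direction of the table are therefore known for 19 samples, and the exact derivation stays unknown for the other 2. The values of these 19 samples were not scaled between slides, whose median log2 intensities ran from 7.884 to 9.35.

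Groups, tests, gene lists, the rule for named genes and the first group of alternatives below were set before the data were examined. Samples were grouped by title and source name, also deficient-diet liver 1, whose treatment field names control parents. Intensities were quantile normalized over the arrays of a tissue, or of both tissues for comparisons between them, summarised per feature by median polish on the log2 scale (10 iterations) and averaged over the 2 arrays of a sample. Normexp background correction with an offset of 50 had been planned where intensities were not already corrected. It was not used for the reported values, because the deposited intensities had already been processed in an unknown way, and it was run with offsets of 0 and 50 as alternatives. Features were kept when above the 95th percentile of the random probes, averaged over the arrays of a sample, in at least 5 samples. This percentile lay between 7.52 and 8.83 log2 in liver and between 6.94 and 8 in kidney. Symbols came from the Entrez identifier for 38545 features and from the accession for 98, and 3932 features had no name.

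Diet groups were compared within each tissue with limma (lmFit and eBayes), which moderates variances over all features, with Benjamini-Hochberg adjusted p under 0.05. The difference between tissues in the diet effect was an interaction contrast over all samples. Kidney and liver of control offspring were compared with the same threshold and an absolute log2 difference of at least 1. All adjusted p-values of genes come from limma. Of 43 gene lists, those with at least 5 measured genes were tested with limma's camera with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Named genes were the 12 with the smallest p in each direction per tissue, and the 4 with the smallest p of each list that passed and of the lists for one-carbon metabolism, DNA methylation, imprinted genes and cholesterol synthesis. The feature with the highest mean level stood for a gene. Tissue markers, Y-linked genes and the 6 leading interaction genes were also named. Some genes that the rule takes in are not reported here, were not replaced, and stayed in all tests and lists. Exact or permutation tests were used for comparisons of single scores. Correlations over samples were given with their rank version and without the 2 farthest samples.

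Alternatives set in advance changed the background correction, the normalization (cyclic loess, median scaling, both tissues together), the probe summary, the filter (none, or the 99th percentile), the variance model, array weights, the slide or sire number as a block, the arrays used, the label of deficient-diet liver 1, the set test and each sample in turn, and used the authors' table. Alternatives added after seeing the data were single slides, pairs of samples that stood apart left out, and covariates for multi-copy gene families and for the difference between kidney slides 6 and 7. Normexp with offset 50, which the plan named for uncorrected intensities, was made an alternative only then. Group labels were reassigned 100 times per comparison, the real assignment included. The code was tested on simulated data with 200 changed features. The files name 8 slides. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.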

Results

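Total RNA of liver and kidney from first-generation BALB/c mice, an inbred laboratory strain, was hybridised to one-colour Cy3 expression arrays. The question was whether the food of the father leaves a mark on gene expression in his offspring. The sires had eaten either control food or a diet poor in methionine with no choline or folic acid, nutrients that feed the pool of methyl groups. The liver samples comprised 5 offspring of control sires and 5 of deficient-diet sires, and the kidney samples comprised 6 and 5. Every sample within a group came from a different sire, named here by the sire's number. The labels do not say how many pups of a sire were used, so p-values measure the spread between these samples. For deficient-diet liver sample 1 the title and source name a treated sire, while its treatment field names control parents. Each sample was read on 2 arrays, described in the labels as technical replicates, giving 42 arrays on 8 slides. Across features the 2 arrays of a sample correlated with r between 0.958 and 0.988. The median intensity of the gene probes on an array ranged from 247 to 695. Of 42575 features, 23920 (12497 named genes) exceeded the level of random probes in liver and 28031 (14547 named genes) in kidney. The median 95% confidence interval of a diet difference reached 0.285 log2 to either side in liver and 0.241 in kidney.

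Kidney and liver of control-sire offspring were first compared, as a check of the tissue labels and of the array's response. Slc34a1, the phosphate transporter of the proximal tubule, and Umod, the uromodulin of the thick ascending limb, were at least 108-fold and at least 109-fold brighter in kidney. Slc12a1, the sodium, potassium and chloride transporter of the loop of Henle, was at least 73.2-fold brighter in kidney. Aqp2, the water channel of the collecting duct, exceeded liver by at least 48.9-fold. These are lower bounds because none of the 5 liver samples rose above background for these genes. Albumin (Alb) fell by 5.80 log2 in kidney relative to liver (SE 0.65, adjusted p = 4.66e-06), from 14.89 ± 0.22 (SD, n = 5) to 9.10 ± 1.67 (SD, n = 6). Apoa1, an apolipoprotein of high-density lipoprotein, differed by -7.89 (SE 0.53, adjusted p = 2.95e-08) and Cps1, the entry enzyme of the urea cycle, by -8.81 (SE 0.41, adjusted p = 7.13e-10), but Apoa1 rose above background in only 2 of 6 kidney samples and Cps1 in 1 of 6, so the sizes of these differences rest on values at background. The wide spread of Alb in kidney came from control kidney 5, without which its difference was -6.47. Ttr, which carries thyroid hormone and retinol, differed by -1.10 (SE 0.11, adjusted p = 2.11e-06).

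Among the gene lists fixed in advance, 15 of 16 hepatocyte markers and 10 of 14 periportal markers were lower in kidney, while 19 of 20 proximal tubule, 13 of 14 loop of Henle and distal tubule, and 15 of 17 collecting duct markers were higher. Of the podocyte markers, 8 of 12 were higher and 1 was lower. Adipocyte markers were higher in kidney for 10 of 13 genes and lower for 1. Perivenous hepatocyte markers divided into 7 lower and 2 higher of 13, and Cyp2e1, a perivenous cytochrome P450, differed by -0.04 (SE 0.08, adjusted p = 0.654). The sign of Cyp2e1 depended on the scaling, since it was 0.18 in the authors' deposited table and -0.59 (adjusted p = 0.000279) after median scaling. Of 27385 features tested with limma, 8165 (29.8%) passed an adjusted p of 0.05 with a difference of at least 1 log2, 4747 higher and 3418 lower in kidney. From the authors' deposited table, in which the median of all features moved by 0.589, the counts were 8162 higher and 1957 lower. No slide carried both tissues, so slide and tissue cannot be told apart.

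**Figure D1:**
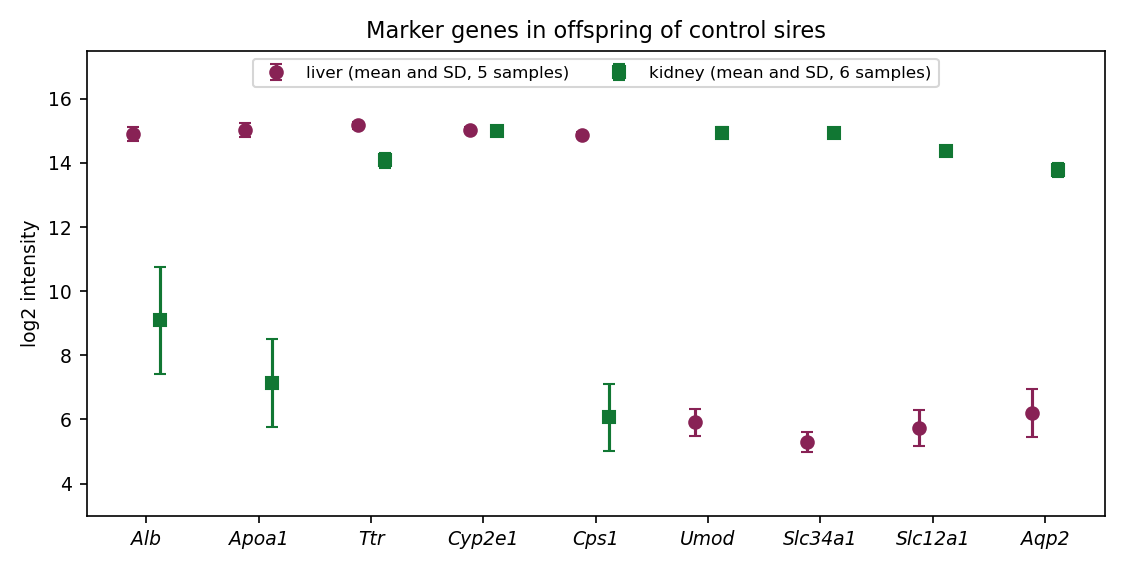
Log2 intensity of 9 marker genes in offspring of control sires, as mean and SD of 5 liver samples (circles) and 6 kidney samples (squares). Alb, Apoa1 and Cps1 were brighter in liver by at least 5.80 log2, whereas Umod, Slc34a1, Slc12a1 and Aqp2 were brighter in kidney and below background in all 5 liver samples.

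In liver, no gene passed the test for a difference between offspring of deficient-diet and control sires. The genes with the smallest p-values were Tatdn2, which encodes a protein with a TatD nuclease domain, and Taf15, an RNA-binding protein associated with the transcription factor TFIID. Tatdn2 measured 9.44 ± 0.36 (SD, n = 5) in control and 10.97 ± 0.47 (SD, n = 5) in deficient-diet offspring, a log2 difference of 1.53 (SE 0.23, adjusted p = 0.186), with 5 of 5 deficient-diet samples above every control. Taf15 measured 9.97 ± 0.28 against 10.82 ± 0.04 (difference 0.85, SE 0.13, adjusted p = 0.186), also with 5 of 5 samples above every control. Fam83a followed with 1.03 (SE 0.18, adjusted p = 0.353) and Taco1, an activator of mitochondrial translation, with 0.75 (SE 0.14, adjusted p = 0.392). Npm3, a histone chaperone of the nucleoplasmin family, differed by 1.11 (SE 0.24, adjusted p = 0.669). The remaining leading genes with higher values were Elmo2 (0.50), Vapb (0.48), Smim5 (0.48), Anapc7, a subunit of the anaphase-promoting complex (0.40), Acrbp (0.44), Cd247 (0.56) and Dnase1l2 (0.47), with adjusted p of 0.544 for Elmo2 and 0.669 for the others. The means of Fam83a and Dnase1l2 lay under the upper end of background in liver (8.83) in both groups, and those of Npm3 and Smim5 in controls. The sizes of these differences are therefore uncertain.

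The leading genes with lower values in deficient-diet liver all had an adjusted p of 0.778. Cyp1a2, the perivenous cytochrome P450 that metabolises caffeine, measured 14.55 ± 0.09 (SD, n = 5) in controls and 14.21 ± 0.09 (SD, n = 5) in deficient-diet offspring, a difference of -0.35 (SE 0.09), with 5 of 5 samples below every control. Ptprb, the receptor phosphatase of vascular endothelium, differed by -0.46 and Adgrl2, an adhesion receptor of the latrophilin family, by -0.51. Mecom, a zinc finger transcription factor, and Igf2bp2, an mRNA-binding protein, each differed by -0.51. Bbof1 (-0.60), Clec2i (-0.60), Gm13212 (-0.61), Zfp874a (-0.58), Gm4910 (-0.53), BC005537 (-0.40) and Cpne1 (-0.35) completed this group. The means of Mecom, Igf2bp2, Bbof1, Clec2i, Gm13212 and Zfp874a lay under the upper end of background in liver (8.83) in both groups. That of Gm4910 did so in deficient-diet offspring. The sizes of their differences are therefore uncertain.

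Of 23920 liver features tested with limma, 0 passed an adjusted p of 0.05, and 1480 had an unadjusted p under 0.05 where 1196 were due by chance. Without control liver 1 this number was 932, below the chance number, and it was 2551 after median scaling and 4084 in the authors' deposited table. With slide as a block, 5 features of 4 genes passed: Npm3 (1.55, adjusted p = 0.00131, and 1.38, adjusted p = 0.0493), Tatdn2 (1.66, adjusted p = 0.00404), Mpst, a sulfurtransferase of cysteine breakdown (1.15, adjusted p = 0.00738), and Fam83a (1.23, adjusted p = 0.0314). Mpst lies outside the rule for named genes and was chosen after its values were seen. The fit with slide as a block used single arrays, with the sample as a random block (consensus correlation 0.228 in liver). It therefore changed the unit as well as the blocking, and its counts do not show the effect of blocking alone. Slides 1, 2 and 4 held 1, 5 and 3 control and 4, 3 and 1 deficient-diet samples. Within them the Tatdn2 difference was 1.72, 1.62 and 1.84, and 0, 0 and 12 features passed. The 12 on slide 4 came from 9 genes, among them the neuronal genes Tubb4a (3.95), Nptxr (3.31) and Syp (2.89), named after their values were seen, and the only deficient-diet sample on that slide was liver sample 5. Without deficient-diet liver 4, 3 features passed, namely Tatdn2 at 1.69 (adjusted p = 0.0485) and 1.89 (adjusted p = 0.0449) and Npm3 at 1.5 (adjusted p = 0.0483). Median scaling, which moved the median of all liver features by 0.148, gave 2 features (Tatdn2 1.68 and Npm3 1.45, both adjusted p = 0.0133). The authors' deposited table, with a shift of 0.265, gave 3 (Tatdn2 1.80, adjusted p = 0.00698, and 1.71, adjusted p = 0.0464, and Npm3 1.34, adjusted p = 0.0289). The Npm3 values of 1.55, 1.5, 1.45 and 1.34 came from another feature than the leading Npm3 value of 1.11. Only the Npm3 value of 1.38 came from that same feature. The Tatdn2 values of 1.89 and 1.71 likewise came from another feature than the leading Tatdn2 value of 1.53.

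The same leading genes also differed between the 2 arrays of single kidney samples. For the 9 kidney samples with an array on both slide 6 and slide 7, Tatdn2 was brighter on slide 6 by 1.94 (SD 0.84), Taf15 by 1.55 (SD 0.66), Npm3 by 1.19 (SD 0.43) and Taco1 by 1.08 (SD 0.36), in 9 of 9 samples each. Of 22 leading liver features measured in kidney, 19 had the sign of the liver diet difference in this slide comparison.

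**Figure D2:**
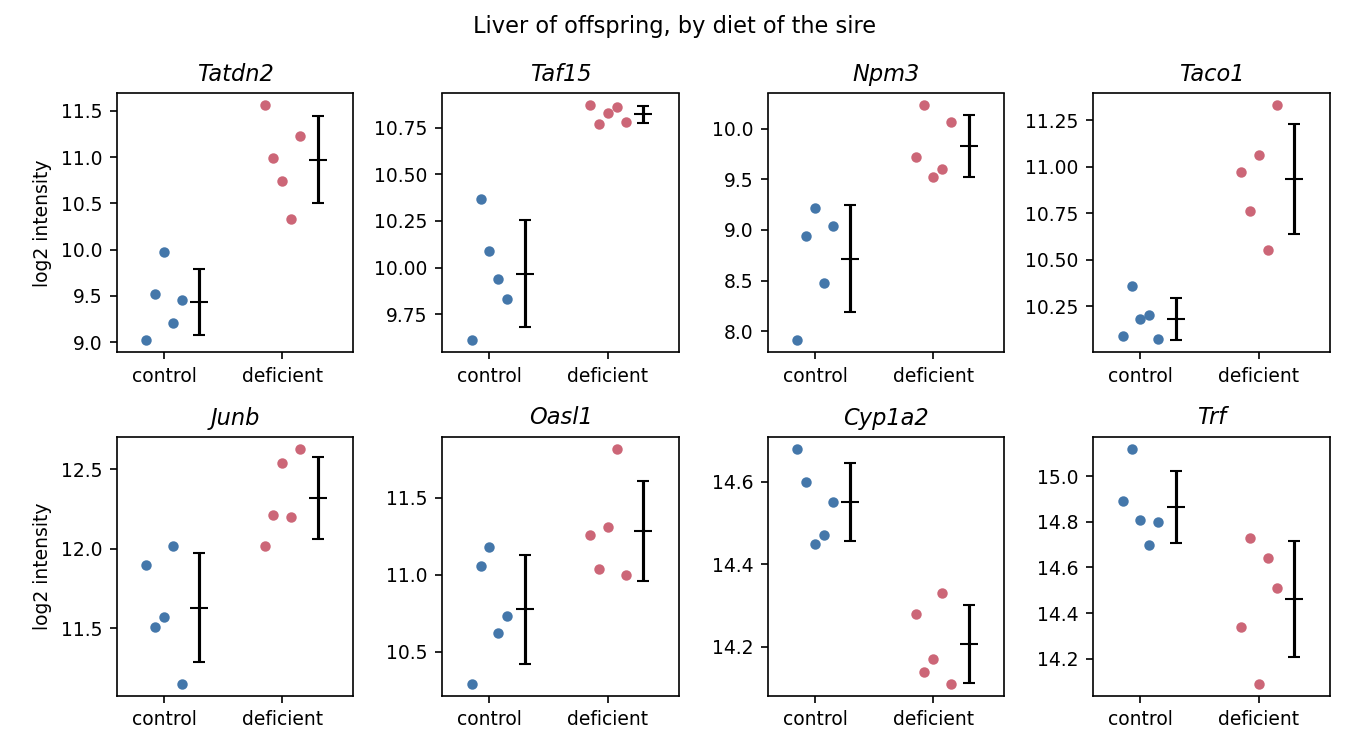
Log2 intensity of 8 genes in liver, 1 point per sample, for 5 offspring of control sires (blue) and 5 of deficient-diet sires (red), with mean and SD as black bars and a separate vertical scale per gene. None passed an adjusted p of 0.05 in limma; all 5 deficient-diet values of Tatdn2, Taf15, Npm3 and Taco1 lay above the control values, and all 5 of Cyp1a2 lay below them.

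**Figure D3:**
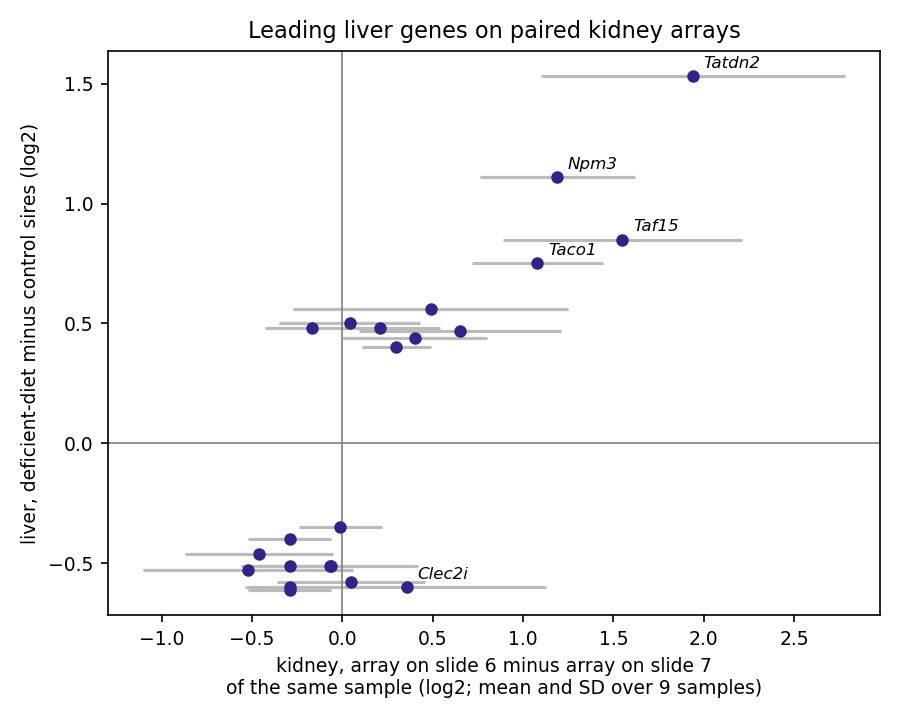
Leading liver features measured in kidney (22 points): the horizontal axis gives the log2 difference between arrays of the same kidney sample on slides 6 and 7 (mean and SD of 9 samples), the vertical axis the log2 diet difference in liver. Tatdn2, Npm3, Taf15 and Taco1 lie at the upper right, between 1.08 and 1.94 on the horizontal axis.

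Although no single gene passed in liver, 7 gene lists passed as groups with the preset correlation. Reassigned labels gave a median of 5 passing lists, and 98 of these reassignments gave at least 1. Passing lists therefore do not by themselves point to the diet. Interferon response genes were higher in deficient-diet offspring for 27 of 31 members (median 0.188, adjusted p = 0.0013 with limma's camera and a preset correlation; adjusted p = 0.648 with an estimated correlation). Oasl1, an oligoadenylate synthetase-like antiviral protein, differed by 0.51 (SE 0.19), Irf7, the master transcription factor of the interferon response, by 0.35 (SE 0.15), Psmb9, an immunoproteasome subunit, by 0.30 and Irgm1, an immunity-related GTPase, by 0.28. Deficient-diet liver 1 was the highest of the 10 liver samples for 23 of 31 interferon genes, where 3.1 were due by chance, with Gbp2 at 10.59 against a mean of 8.87 (SD 0.38, n = 9) in the others. Without this sample the list median was 0.068 (adjusted p = 0.407), and with it counted as a control offspring, as its treatment field says, -0.036 (adjusted p = 0.433). Its lymphocyte marker score (0.293) was the highest of the 10 livers, and its macrophage marker score (0.342) was exceeded only by deficient-diet liver 4 (0.393), which had the next highest interferon score (0.296).

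Cell cycle genes were higher for 25 of 29 members (median 0.178, adjusted p = 0.00292; adjusted p = 0.648 with an estimated correlation). Stmn1, a microtubule-destabilising protein, differed by 0.41 (SE 0.15), Aurkb, a mitotic kinase, by 0.63 (SE 0.27), and Mcm7 and Mcm2, subunits of the replicative helicase, by 0.21 and 0.27. This call ended without deficient-diet liver 4 (median 0.127, adjusted p = 0.303) and without control liver 4 (0.153, adjusted p = 0.0641), and the median was 0.109 without control liver 1 and 0.312 without deficient-diet liver 5. Deficient-diet liver 4 had the highest scores of the 10 livers for cell cycle genes (0.506) and for erythroid markers (0.486), and the erythroid list was higher in 5 of 5 members (median 0.222, adjusted p = 0.0879). Immediate early genes were higher for 13 of 17 members (median 0.178, adjusted p = 0.00825; adjusted p = 0.556 with an estimated correlation). Junb, a component of the AP-1 transcription factor, measured 11.63 ± 0.35 (SD, n = 5) in controls and 12.32 ± 0.26 (SD, n = 5) in deficient-diet offspring (difference 0.69, SE 0.17). Nr4a1, an inducible orphan nuclear receptor, differed by 0.56 (SE 0.15), Fos by 0.65 (SE 0.33) and Ier5 by 0.28 (SE 0.12). The means of Fos and Aurkb lay under the upper end of background in liver (8.83) in both groups, and those of Nr4a1 and Ier5 in controls. The sizes of the differences of these 4 genes are therefore uncertain. Junb and Nr4a1 were the 2 genes past the test when adjusted over the list alone, and 0 passed over all genes. Without deficient-diet liver 2 the list had a median of 0.143 (adjusted p = 0.0598).

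The lists that moved to lower values were markers of liver cell types and of drug metabolism. Endothelial markers were lower for 16 of 18 members (median -0.214, adjusted p = 0.0013; adjusted p = 0.648 with an estimated correlation). The scavenger receptors of sinusoidal endothelium Stab1 and Stab2 differed by -0.47 (SE 0.17; 0.02 for the other Stab1 feature) and -0.28 (SE 0.18), and Flt4, a receptor of vascular endothelial growth factor, by -0.42 (SE 0.19), while Vwf, von Willebrand factor of larger vessels, differed by 0.21 (SE 0.09). Fibroblast and stellate cell markers were lower for 16 of 19 members (median -0.182, adjusted p = 0.00284; adjusted p = 0.648 with an estimated correlation). Lrat, which forms the retinyl esters stored in stellate cells, differed by -0.54 (SE 0.22), Mgp, an inhibitor of calcification, by -0.55 (SE 0.27), the matrix protein Postn by -0.27 and the intermediate filament protein Des by -0.36. The Des means of both groups and the Mgp mean of deficient-diet offspring lay under the upper end of background in liver (8.83). The sizes for Des and Mgp are therefore uncertain. Both calls rested on deficient-diet liver 5: without it the medians were -0.072 (adjusted p = 0.0945) for endothelial and -0.008 (adjusted p = 0.234) for fibroblast and stellate cell markers. The endothelial call also ended without deficient-diet liver 2 (-0.177, adjusted p = 0.0598). The fibroblast and stellate cell median was -0.114 without control liver 4, -0.112 without deficient-diet liver 2 and -0.275 without deficient-diet liver 4.

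Hepatocyte markers were lower for 14 of 16 members (median -0.106, adjusted p = 0.0013; adjusted p = 0.648 with an estimated correlation). Trf, the iron carrier transferrin, measured 14.86 ± 0.16 (SD, n = 5) against 14.46 ± 0.25 (SD, n = 5), a difference of -0.40 (SE 0.13). Ttr and Serpina1a, an antitrypsin, each differed by -0.22, and Cyp2e1 by -0.19. This call ended without deficient-diet liver 3 (-0.059, adjusted p = 0.0578), and the median was -0.061 without deficient-diet liver 1 and -0.168 without deficient-diet liver 2. Xenobiotic metabolism genes were lower for 26 of 35 members (median -0.098, adjusted p = 0.00141; adjusted p = 0.648 with an estimated correlation), led by Cyp1a2 (-0.35), Cyp2c29 (-0.20), Cyp2e1 (-0.19) and Ugt2b5 (-0.17). Their median was -0.046 without control liver 5 and -0.065 without deficient-diet liver 5. These directions are relative to the bulk of genes. In the authors' deposited table, where the median of all features moved by 0.265, the medians were 0.041 for endothelial, 0.064 for fibroblast and stellate cell, 0.067 for hepatocyte and 0.159 for xenobiotic genes. That table was not scaled between slides, which held the diet groups in unequal numbers. These signs therefore cannot be told apart from slide differences. After median scaling, with a shift of 0.148, the xenobiotic median was 0.032.

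Of 36 lists tested in liver, 7 passed. With deficient-diet liver 1 counted as a control offspring 6 passed, 3 of them among the 7, and the cell cycle (0.161, adjusted p = 0.0533), hepatocyte (-0.045, adjusted p = 0.0859) and fibroblast and stellate cell calls (-0.223, adjusted p = 0.0586) ended beside the interferon call. The cell cycle and immediate early calls ended with median scaling (medians 0.291 and 0.333, adjusted p = 0.0861 and 0.0798), in the authors' deposited table (0.362 and 0.462, adjusted p = 0.234 and 0.296) and with the 99th percentile filter (0.14 and 0.17, adjusted p = 0.152 and 0.0749). From the first array only, the immediate early call ended (0.185, adjusted p = 0.0595). From the second, the cell cycle (0.206, adjusted p = 0.0654), hepatocyte (-0.05, adjusted p = 0.067) and fibroblast and stellate cell calls (-0.166, adjusted p = 0.0661) ended. With slide as a block the interferon median was 0.163 (adjusted p = 0.0125), immediate early 0.188 (adjusted p = 0.0204), endothelial -0.302 (adjusted p = 4.75e-06), fibroblast and stellate cell -0.251 (adjusted p = 7.2e-05) and xenobiotic -0.084 (adjusted p = 0.0204). The blocked cell cycle median was 0.15 (adjusted p = 0.0648) and the hepatocyte median 0.018 (adjusted p = 0.818). These blocked list p-values came from sample values after slide effects had been removed, in a fit without a slide term, so they may be too small. Within slides 1, 2 and 4 the medians were 0.130, 0.292 and -0.105 for interferon, 0.278, 0.291 and -0.129 for cell cycle, and 0.141, 0.183 and 0.104 for immediate early genes. The corresponding values were -0.216, -0.138 and -0.764 for endothelial, -0.401, -0.030 and -0.508 for fibroblast and stellate cell, -0.013, 0.004 and 0.008 for hepatocyte and -0.170, -0.062 and -0.004 for xenobiotic genes.

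Lists tied to the diet's nutrients did not pass in liver. One-carbon and methionine metabolism had 25 of 40 members with higher values (median 0.046, adjusted p = 0.432). Its leading members were Mthfd2, the mitochondrial folate enzyme (0.47, SE 0.13), Tyms, which makes thymidylate (-0.27), Slc46a1, the proton-coupled folate transporter (0.19), and Gldc of the glycine cleavage system (-0.21). DNA methylation and demethylation genes had a median of 0.030 (14 measured, adjusted p = 0.918), with the methyl-CpG reader Mbd2 at -0.18, the dioxygenase Tet2 at 0.17, the methyltransferase Dnmt3b at 0.38 and Uhrf1, a reader of hemimethylated DNA, at 0.25. Imprinted genes had a median of 0.009 (22 measured, adjusted p = 0.977), with Tssc4 at 0.33, Nnat at 0.53, Slc22a3 at 0.32 and Plagl1 at -0.31. Cholesterol synthesis genes were higher for 19 of 25 members (median 0.133, adjusted p = 0.0625), among them Pmvk (0.31) and Mvd (0.26) of the mevalonate pathway and the squalene synthase Fdft1 (0.33). The means of Tyms and Dnmt3b lay under the upper end of background in liver (8.83) in both groups. Those of Mthfd2, Uhrf1 and Fdft1 did so in controls and that of Plagl1 in deficient-diet offspring, so these sizes are uncertain. The sign of Mbd2 depended on the scaling, at 0.04 after median scaling and 0.21 in the authors' deposited table, where Tyms and Gldc were 0.07 and 0.12. Over the list alone 1 gene passed among glucose metabolism genes, the insulin receptor Insr (0.50, SE 0.13), 1 among perivenous markers, Cyp1a2, and 1 among the 3 measured loop of Henle and distal tubule markers, the channel kinase Trpm7 (-0.31, SE 0.11), and 0 passed over all genes. Insr and Trpm7 were named after their values were seen. The 29 liver lists that did not pass had medians between -0.175 and 0.222. Of the 36 genes named in liver with other measured features, all of these had the direction of the named one in 30, all the opposite in 3 (Stab1 0.02, BC005537 0.04, Mbd2 0.61) and some in 3 (Vapb -0.23, Ttr 0.16, Serpina1a 0.30).

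**Figure D4:**
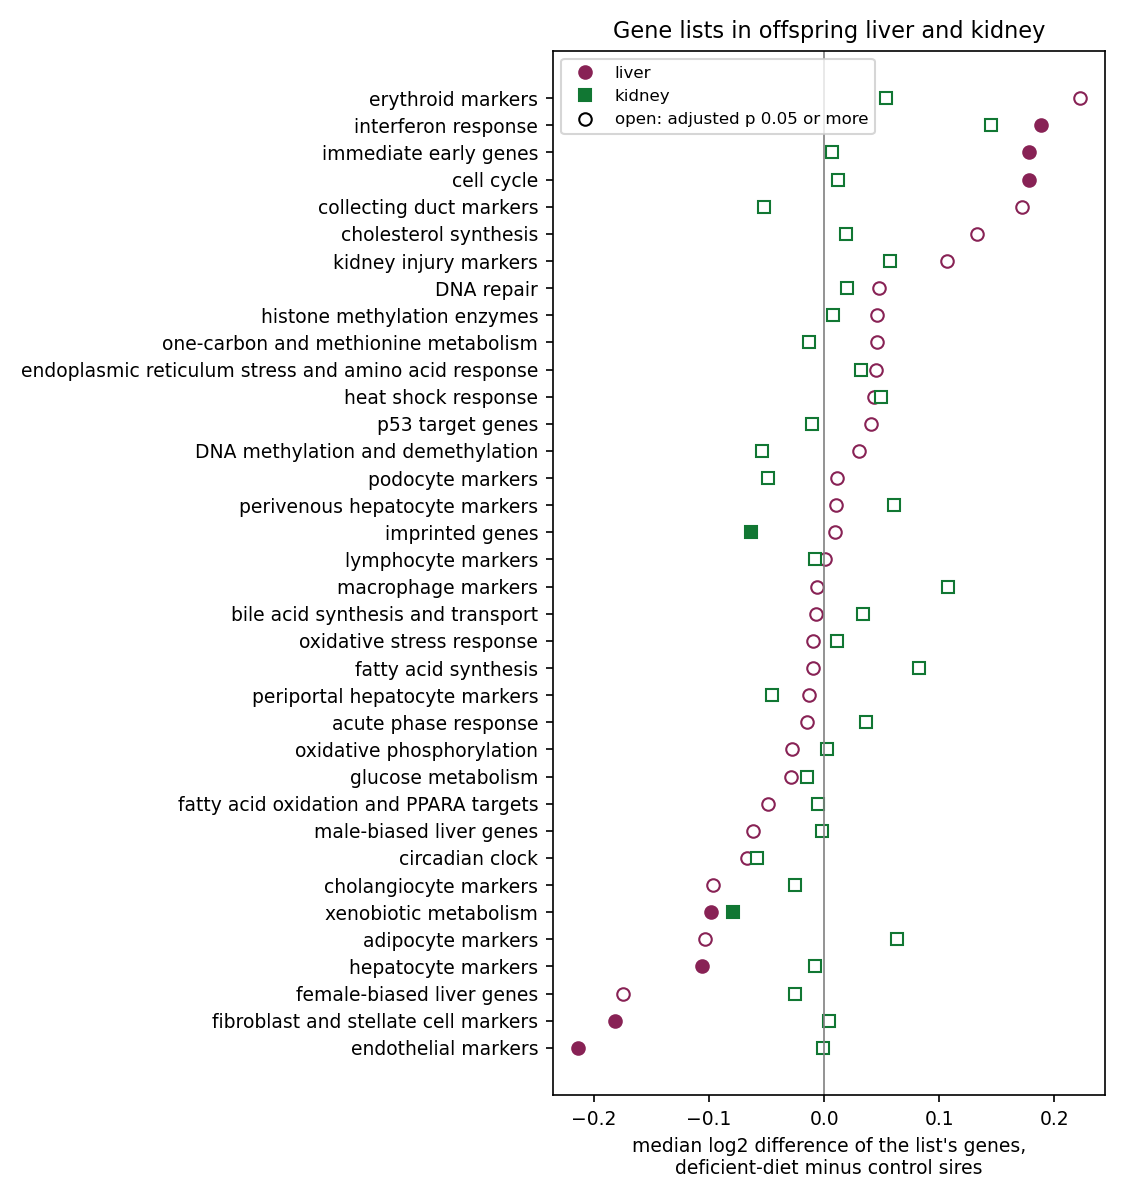
Median log2 difference between deficient-diet and control offspring for the lists tested in both tissues, in liver (circles, n = 5 and 5) and kidney (squares, n = 6 and 5). Filled symbols passed an adjusted p of 0.05 with a preset correlation, 7 lists in liver and 2 in kidney, and 0 passed with an estimated correlation; 4 of the liver medians on the left lie above 0 in the authors' deposited table.

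Several samples carried transcripts that set them apart from the rest of their tissue. In deficient-diet liver 5, 591 features lay more than 1 log2 above every other liver sample on both arrays, among them the cerebellar granule cell genes Cbln1 (12.35 against at most 7 on any other liver array), Cbln3 (11.50 against 6.36), Neurod1 (10.43 against 5.13) and Gabra6 (9.78 against 4.92), and the synaptic gene Snap25 (13.27 against 8.65). In control liver 5 there were 21 such features, including, against the brightest array of any other liver, Muc3 (10.90 against 5.50), Slc26a3 (8.01 against 5.80) and Dmbt1 (14.02 against 10.45), genes of the intestinal and bile duct lining. In deficient-diet liver 4 there were 15, including the red cell genes Slc4a1 (9.64 against 8.15) and Kel (6.96 against 5.21). Control liver 1 had 307, among them the vomeronasal receptors Vmn1r148 (9.21 against 7.01) and Vmn1r160 (9.13 against 6.79). With control liver 5 and deficient-diet liver 5 both left out, a choice made after seeing the data, 0 liver genes passed and 5 lists passed, with endothelial at -0.072 (adjusted p = 0.0979) and fibroblast and stellate cell at -0.018 (adjusted p = 0.309) no longer among them. The genes of this paragraph were chosen after their values were seen.

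In kidney, no gene passed the test for a difference between offspring of deficient-diet and control sires, and every named gene had an adjusted p of 1. Igkv4-56, an immunoglobulin light-chain segment, measured 8.60 ± 0.26 (SD, n = 6) in controls and 9.16 ± 0.26 (SD, n = 5) in deficient-diet offspring, a difference of 0.56 (SE 0.15). Timp1, a secreted inhibitor of metalloproteinases, differed by 0.47 (SE 0.12). Its means of 6.97 in controls and 7.43 in deficient-diet offspring lay within the range of background in kidney (6.94 to 8), so this size is uncertain. Cyp2a5, a xenobiotic cytochrome P450, measured 8.16 ± 0.23 (SD, n = 6) against 7.59 ± 0.36 (SD, n = 5), a difference of -0.57 (SE 0.16). Its deficient-diet mean lay within the same range of background, so this size is also uncertain. Rab27a, a small GTPase of vesicle secretion, differed by -0.33 (SE 0.08) and Ntf3, the neurotrophin 3 gene, by -0.26.

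The other leading kidney genes with higher values were Gm9372 (0.49), Fabp5l2 (0.34), Snhg16 (0.33), Gm9776 (0.32), Zfp74 (0.30), Cox7a1 (0.29), Pcsk5 (0.28), Tmem242 (0.28) and 5031425E22Rik (0.22). Those with lower values were Mrgprf (-0.50), E130102H24Rik (-0.38), Supt6 (-0.31), Sned1 (-0.28), 2500004C02Rik (-0.27), Reep6 (-0.26), Il10rb (-0.26), Cldnd1 (-0.24) and Tmem86b (-0.23). Of 28031 features tested with limma, 0 passed an adjusted p of 0.05 and 787 had an unadjusted p under 0.05, fewer than the 1401.55 due by chance. This number was 1201 without control kidney 2, 427 in the authors' deposited table, and above the chance number with array weights (1577) and from the second array only (1703). With slide as a block 0 passed and 813 had an unadjusted p under 0.05, and within slides 6 and 7 the passing counts were 0 and 0, with 1999 and 441 at an unadjusted p under 0.05. Within slides the Timp1 difference was 0.72 on slide 6 and 0.08 on slide 7, and the Rab27a difference -0.44 and -0.18. In simulated data with this number of samples and planted changes, limma recovered 82.9% of kidney features changed by 1 log2. It recovered 46.0% of those changed by 0.5, and in liver 85.3% and 38.7%. Whether these rates hold for the real samples was not tested. In the real liver data Tatdn2 at 1.53 (adjusted p = 0.186) and Npm3 at 1.11 (adjusted p = 0.669) did not pass with limma. The rates therefore do not exclude differences of 1 log2 among the genes that did not pass.

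Genes of the imprinted list, which are expressed from 1 parental copy in some tissues, were lower in deficient-diet kidney for 18 of 26 members (median -0.064, adjusted p = 0.033; adjusted p = 0.89 with an estimated correlation). Expression by parental copy was not measured. The paternally expressed Peg3 and Snrpn differed by -0.23 (SE 0.08) and -0.19 (SE 0.08), Ube3a, a ubiquitin ligase, by -0.26 (SE 0.12) and Slc22a2, the renal organic cation transporter, by -0.14 (SE 0.09). Xenobiotic metabolism genes were lower for 18 of 24 members (median -0.079, adjusted p = 0.033; adjusted p = 0.89 with an estimated correlation). Beside Cyp2a5, the bilirubin-conjugating Ugt1a1 differed by -0.20 (SE 0.09), Cyp1a1 by -0.24 (SE 0.12) and the glutathione transferase Gstp1 by -0.14 (SE 0.08). The Cyp1a1 means, 7.94 in controls and 7.70 in deficient-diet offspring, lay within the range of background in kidney (6.94 to 8), so this size is uncertain. Both calls ended with slide as a block, at -0.051 (adjusted p = 0.327) for imprinted and -0.042 (adjusted p = 0.382) for xenobiotic genes. Within slides 6 and 7 the medians were -0.039 and -0.066 for imprinted and 0.012 and -0.096 for xenobiotic genes. Without deficient-diet kidney 5 the medians were -0.028 and -0.024, both with an adjusted p of 0.282. Without control kidney 2 they were -0.067 (adjusted p = 0.0856) and -0.060 (adjusted p = 0.183), and without control kidney 3 they were -0.061 (adjusted p = 0.0636) and -0.055 (adjusted p = 0.0831). The imprinted call also ended without control kidney 1 (-0.042, adjusted p = 0.071). In all, 0 lists passed without control kidney 2 or control kidney 3, 1 passed without deficient-diet kidney 5 and 5 passed without deficient-diet kidney 3.

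The remaining 36 kidney lists tested did not pass. Interferon response genes had higher values in 22 of 28 members (median 0.145, adjusted p = 0.0549), and deficient-diet kidney 1 was the highest of 11 kidney samples for 27 of 28 genes, where 2.5 were due by chance. Its macrophage (0.374) and lymphocyte marker scores (0.306) were also the highest of the 11 kidneys. In that sample Iigp1, an interferon-inducible GTPase, stood at 13.13 against a mean of 10.50 (SD 0.33, n = 10) in the others, and Tap1, the peptide transporter of antigen presentation, at 12.28 against 10.42 (SD 0.22, n = 10). One-carbon and methionine metabolism genes had a median of -0.013 (41 measured, adjusted p = 0.842), with Atic at -0.15, Aldh1l2 at -0.27, the methionine synthase Mtr at 0.17 and Aldh1l1 at 0.12. DNA methylation and demethylation genes had a median of -0.054 (17 measured, adjusted p = 0.422), with Tet3 at -0.16, Tdg at -0.21, Zfp57, a keeper of imprints, at -0.22 and Mbd2 at 0.11. Cholesterol synthesis genes had a median of 0.019 (25 measured, adjusted p = 0.59), with Pmvk at -0.16. Of the 17 genes named in kidney with other measured features, all of these had the direction of the named one in 10, all the opposite in 6 (Pcsk5 -0.06, Tmem242 -0.12 and -0.02, Rab27a 0.14, Supt6 0.06, Ugt1a1 0.02, Pmvk 0.16) and some in 1 (Il10rb 0.07). Among kidney injury markers 1 gene, Timp1, passed when adjusted over the list alone, and 0 passed over all genes. The Timp1 means of both groups lay within the range of background.

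**Figure D5:**
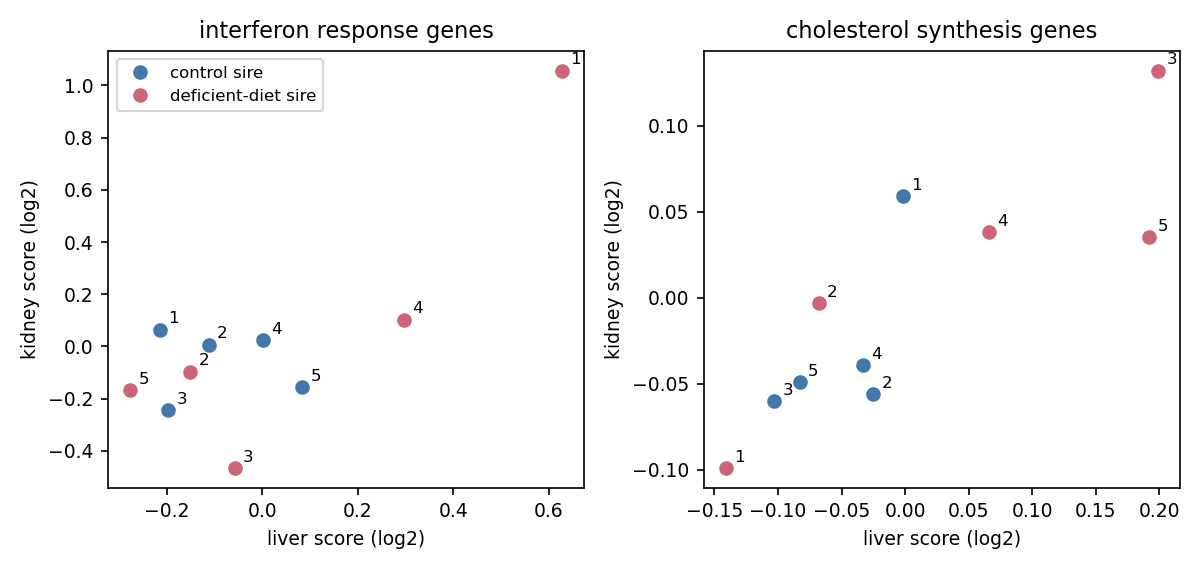
Mean log2 score of the interferon response genes (left) and cholesterol synthesis genes (right) in liver (horizontal axis) and kidney (vertical axis), 1 point per sire number, for 5 control (blue) and 5 deficient-diet sires (red). Deficient-diet sire 1 stands apart for interferon genes, at 0.628 in liver and 1.057 in kidney.

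Control kidney 5 carried hepatocyte transcripts and control kidney 4 had low Y-linked ones. In control kidney 5 Alb stood at 12.62 against 8.50 to 9.04 in the other 10 kidney samples, Apoa1 at 10.41 against 6.51 to 7.16 and Fgb, a fibrinogen chain, at 8.04 against 4.56 to 5.36. In control kidney 4 the Y-linked Ddx3y stood at 9.74 against a mean of 11.17 (SD 0.07, n = 10), Kdm5d at 9.24 against 10.69 (SD 0.18, n = 10), Uty at 9.37 against 10.64 (SD 0.30, n = 10) and Eif2s3y at 10.42 against 11.54 (SD 0.19, n = 10). No feature was named Xist. Liver from control sire 4 had Ddx3y at 11.71, near the mean of 11.45 in the other liver samples. With both of these kidney samples left out, a choice made after seeing the data, 0 kidney genes and 3 kidney lists passed.

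The diet differences of liver and kidney were then compared directly. With both tissues scaled together, genes with a small p for a different response included Nags, which makes the activator of Cps1 (0.17 in liver, interaction -0.69, SE 0.16), Lysmd1 (0.36 in liver and -0.21 in kidney, interaction -0.57, SE 0.13) and Igkv4-56 (-0.58 and 0.56, interaction 1.14, SE 0.28). Nags was above background in 0 of 11 kidney samples and Igkv4-56 in 3 of 10 liver samples, so their interaction values rest on differences at background. Smim5 followed (0.60 and 0.01, interaction -0.60, SE 0.15), then Wrap73 (0.32 and -0.11, interaction -0.43, SE 0.11). All of these had an adjusted p of 0.977. Of 28968 features tested with limma over all 21 samples, 0 passed, with a smallest adjusted p of 0.531, and 1335 had an unadjusted p under 0.05 where 1448.4 were due by chance (2003 without deficient-diet liver 2, and 4825 in the authors' deposited table, where the median of all features moved by -0.326). Across 22966 features measured in both tissues the diet differences correlated with Pearson r of 0.0522 and Spearman rho of 0.0700, and 52.7% had the same sign. Features are not independent replicates, so no p-value was computed from them. The correlation ranged from -0.0309 to 0.138 when 1 sample was left out.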

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

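The tests by reassigned labels were set in advance, and the other tests in this part were chosen only after the results were seen. Of 390 groups of values examined, 26 held a sample far from the others of its group, where chance flags about 1 in 20 groups and 19.5 were due. The gap to the nearest sample over the range of the group is given for each. In control liver it was 0.734 for Elmo2 (sample 1 above), 0.770 for Gm4910 (sample 4 below), 0.784 for Tet2 (sample 4 above), 0.734 for male-biased liver genes (sample 4 below) and 0.764 for collecting duct markers (sample 1 below). In deficient-diet liver it was 0.712 for Fam83a (sample 4 below), 0.849 for Mbd2 (sample 1 below), 0.831 for Uhrf1 (sample 5 below) and 0.734 for periportal markers (sample 5 above). In control kidney it was 0.628 for Aldh1l1 (sample 5 below), 0.899 for Ddx3y, 0.636 for Eif2s3y, 0.686 for Kdm5d and 0.639 for Uty (sample 4 below), 0.713 for female-biased liver genes (sample 4 above) and 0.725 for hepatocyte markers (sample 5 above). In deficient-diet kidney it was 0.780 for Zfp74 (sample 5 above), 0.758 for Ntf3 (sample 4 above), 0.741 for Zfp57 (sample 3 below), 0.732 for DNA methylation genes (sample 4 above), 0.712 for imprinted genes and 0.726 for proximal tubule markers (sample 5 below) and 0.828 for circadian clock genes (sample 4 below). In the tissue comparison it was 0.884 for Alb, 0.836 for Apoa1 and 0.901 for Cps1 (control kidney 5 above).

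With a real count of 0, all 100 of 100 splits give at least as many, so the splits decide nothing for liver features (highest other 3), kidney features (highest other 167) or the interaction (highest other 9). Chance cannot be excluded for the 1480 liver features at an unadjusted p under 0.05 (23 of 100 splits gave as many, highest other 2798) or for the 7 liver lists (21 of 100, highest other 9). In kidney the counts were 78 of 100 for the 787 features at an unadjusted p under 0.05 (highest other 3086) and 80 of 100 for the 2 lists (highest other 11), and chance cannot be excluded. The other splits gave a median of 5 lists in liver and 4 in kidney, and 98 and 89 of them gave at least 1 list. The split with 167 features, the only 1 drawn that called any in kidney, may point to a structure of the samples, which was not tested. For the correlation of diet effects 28 of 100 splits gave one as high as 0.0522 (highest other 0.366, lowest -0.245), and chance cannot be excluded. Chance can be excluded for the 8165 features between kidney and liver (1 of 100, highest other 6903 in a split that exchanged all but 1 kidney sample).

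The first pattern is that leading liver genes differed between arrays of the same kidney samples on slides 6 and 7. Over 22 leading features the median slide difference in the direction of the liver effect was 0.569 of the median liver effect, so labelling or hybridisation differences may contribute to the liver values. Over 22966 features the slide difference correlated with the liver diet effect at r = 0.407 (rho 0.307), and 3 of 126 splits of the liver samples, the real one included, were as far from 0 (highest other 0.422). The slide that held a liver array is excluded as the whole cause, because the effects with slide as a block were 1.05 times the unblocked ones. The position of an array within its slide was not tested and cannot be told apart from diet. On slide 2 control arrays lay at positions 2, 4, 8, 10 and 12 and deficient-diet arrays at 1, 3, 5 and 9. For the difference between liver groups the diet of the sire cannot be told apart, since a score of the features that differ most between the slides differed by 0.99 in liver (exact p = 0.0238) and by -0.01 in kidney (exact p = 0.963).

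The second pattern is transcripts of other tissues in single samples, for which no biological explanation was tested. In control kidney 5, 33.7% of 433 liver-abundant features were the highest of 11 samples (9.09% by chance), with a median excess of 0.175% of the liver level, so a trace of liver RNA may be present but is not established. A fault of 1 array is excluded, since the smaller array mean of the excess was 0.575 log2. In deficient-diet liver 5, 44% of 25 Purkinje cell, oligodendrocyte and Bergmann glia markers were highest on both arrays (Pcp2 9.21, Mobp 10.13), against 1 of 14 forebrain markers. Cerebellar RNA is a candidate source that these values leave open.

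The third pattern is that multi-copy gene families varied together between kidney samples, Vmn1r from 5.84 to 7 and Ssty from 7.63 to 12.56. Their means correlated with r = 0.944 (permutation p = 1e-05, the smallest that the resamples can give; rho 0.945; 0.939 without the 2 farthest samples). Genomic DNA in the labelled material may be a cause but cannot be told apart, because the spread of Vmn1r was only 1.13 times that of olfactory receptor features and that of Ssty 4.39 times. Both families were lowest in control kidney 4, which also had low Y-linked transcripts, and Ssty is Y-linked. The next lowest Ssty mean was 10.74, in control kidney 1. Ratios without control kidney 4 were not computed. Array background, measured by the random probes, did not rise with Vmn1r (r = -0.618, rho -0.309, -0.127 without the 2 farthest samples). This does not exclude it, because the samples are few and Vmn1r lay at or under the level of the random probes. The diet of the sire is excluded as the whole cause, since r stayed at 0.941 after removing the means of the diet groups. The Vmn1r mean also correlated with the first principal component of the kidney samples, which held 34.2% of the variance. There r was 0.926 (permutation p = 9e-05, rho 0.864, 0.795 without the 2 farthest samples).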

How the results depend on the processing

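Kidney genes and the interaction stayed at 0 under every alternative run, while 0 to 5 liver features passed under those set in advance. Slide 4 alone, single slides, pairs left out and covariates were chosen after seeing the data. Normexp with offset 50, planned for uncorrected intensities, became an alternative only then. Liver features numbered 2 with median scaling, 3 in the authors' table, 5 with slide as a block, 12 on slide 4 alone and 0 to 3 without 1 sample. Liver lists numbered 4 from the second array only, 0 with an estimated correlation, 0 with fry and 4 with the slide 6 to 7 score as covariate. The covariate ended the cell cycle call at a median of 0.174 and the immediate early call at 0.181, both adjusted p = 0.0548. It also ended the xenobiotic call at -0.112 (adjusted p = 0.0813) and the hepatocyte call at 0.024 (adjusted p = 0.999). Liver lists numbered 6 with deficient-diet liver 1 counted as control, 6 to 9 without 1 sample and 5 on slide 2, of which 3 were among the 7 reported. Slide 1 held 1 control sample and slide 4 held 1 deficient-diet sample, so no list count is given for them. Kidney lists numbered 0 with median scaling, probe means, the 99th percentile filter, slide as a block, the second array, an estimated correlation, fry, slide 6 and slide 7, and 0 to 5 without 1 sample. From the first array 2 passed without the imprinted list (-0.065, adjusted p = 0.203), and with the authors' values 3 passed without the xenobiotic list (-0.171, adjusted p = 0.0541). The tissue count ranged from 8079 to 10119 under alternatives set in advance, from 8050 to 8439 without 1 sample and was 7596 with normexp and offset 50. The correlation of diet effects ranged from -0.059 (no filter) to 0.0699 under alternatives set in advance, was 0.00754 and 0.0743 with the liver or kidney pair left out, and ranged from -0.0309 to 0.138 without 1 sample. With the sire number as a replicate block, 0 liver genes, 7 liver lists, 0 kidney genes and 3 kidney lists passed. Control and deficient-diet deviations of the same number correlated over 0.1 in 1 of 5 pairs in liver (-0.172 to 0.309) and in 3 of 5 in kidney (0.529, 0.184 and 0.32, each the best match; lowest -0.18), so no pairing was assumed, as not every pair did. Changes in the authors' table can come from slides that were not scaled to each other, and the cause of the other changes was not tested.

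These values turned direction, and the cause was not tested. Direction of the list test, relative to other genes, with the median: liver interferon with deficient-diet liver 1 counted as control (-0.036) and on slide 4 (-0.105), hepatocyte on slides 1 (-0.013) and 2 (0.004) and with the score covariate (0.024), cell cycle on slide 4 (-0.129). Sign of the median only: hepatocyte with slide as a block (0.018), on slide 4 (0.008) and in the authors' table (0.067), xenobiotic with median scaling (0.032) and in the authors' table (0.159), endothelial (0.041) and fibroblast and stellate cell (0.064) in the authors' table, kidney xenobiotic on slide 6 (0.012). Authors' table, liver: BC005537 0.06, Cpne1 0.02, Cyp2c29 0.02, Cyp2e1 0.09, Ugt2b5 0.09, Serpina1a 0.03, Stab2 0.04, Tyms 0.07, Gldc 0.12, Mbd2 0.21; tissue: Cyp2e1 0.18. Median scaling: Mbd2 0.04. Slide 1: Gm4910 0.02, Vwf -0.06, Tet2 -0.12, Dnmt3b -0.17. Slide 2: Clec2i 0.05, Tet2 -0.01. Slide 4: Cpne1 0.02, Gm4910 0.09, Cyp2c29 0.12, Cyp2e1 0.05, Mcm2 -0.12, Tyms 0.05, Gldc 0.26, Uhrf1 -0.65, Slc22a3 -0.30. Kidney: Slc22a2 0.05 with both tissues together, Gm9776 -0.01 and Mtr -0.02 from the first array, and on slide 7 Atic 0.02, Mtr -0.05, Tet3 0.05, Tdg 0.07. Tissue Cyp2e1 was 0 with the sire number as a replicate block and -0.07 to 0 without 1 sample, 0 being without control kidney 6. Of all named-gene values, 2079 of 2111 in liver, 1192 of 1199 in kidney and 158 of 162 between tissues kept direction and side of the threshold. In the diet comparisons 0 genes passed with the reported processing, so there keeping the side meant not passing. The settings counted include no background correction, which repeats the reported processing. These shares therefore do not measure how firm the diet differences are.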

Other observations

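The tests in this part were all chosen after the results were seen. Cholesterol synthesis genes had related scores in liver and kidney of the same sire number, with r = 0.845 over 10 sires (permutation p = 0.001, adjusted p = 0.036 over 36 lists; rho 0.867, adjusted p = 0.0432; 0.802 without the 2 farthest sires; 0.817 after removing the means of the diet groups). For fatty acid synthesis genes r was 0.819 (permutation p = 0.0051, adjusted p = 0.0918; 0.6 without the 2 farthest sires) and rho 0.903 (adjusted p = 0.0216). For interferon response genes r was 0.798 (permutation p = 0.021, adjusted p = 0.252; rho 0.491, adjusted p = 0.72), falling to -0.0751 without the 2 farthest sires. A candidate explanation is that liver and kidney of 1 sire number came from the same animal or litter, which the labels do not say. Over all genes the mean correlation of same-sire deviations was 0.00981 (permutation p = 0.43), which leaves this open.

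Deviations of the 2 arrays of a sample from the mean of their tissue correlated with a median r of 0.219 in liver and 0.229 in kidney, and 12 of 20 liver arrays and 6 of 22 kidney arrays were closest to their own pair. In control kidney 4, Prlr stood at 10.42 against a mean of 8.60 in the other kidneys and Slc7a12 at 10.88 against 9.41, while the male-biased Cyp4a12a stood at 14.39 against 14.49 and Cyp4a12b at 14.62 against 14.43. Of 14547 genes kept in kidney, 289 were lower there by at least 1.35 log2, the median drop of the 4 Y-linked genes.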
